A study of Mus musculus with 5 samples.

How the data were processed

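The data were 5 samples of sorted mouse bone marrow cells profiled with the 10x Genomics single-cell 3' kit and sequenced on an Illumina HiSeq, per the labels' protocols. The deposited matrices hold raw counts of UMIs per gene and barcode, not normalized. The submitters' processing notes list CASAVA 1.8.2, Cell Ranger 2.0.0, Seurat 2.3.0 and the mm10 build, and the filters on cells are not given in the sources used here. Samples were grouped by the sort gate in the labels into LSK, CMP, GMP and MEP. The 2 CMP samples held identical matrices, 3738 barcodes and 27010594 UMIs each, and were used once. The remaining CMP cells of the 12185 that the design text states were not analysed here.

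The GMP and MEP matrices held the stated numbers of cells, 8064 and 6370. The LSK matrix held 737280 barcodes, so the 10882 barcodes with the most UMIs were taken as cells, as many as the design text states. The lowest of them had 2110 UMIs, and the barcode at rank 12000 had 647. Cells with 500 or more genes and at most 10% mitochondrial UMIs were kept, which left 10870 LSK, 3713 CMP, 8027 GMP and 6284 MEP cells with 75167959, 26919088, 73362645 and 80273121 UMIs. Library totals over these cells were used for the gene contrasts, so that doublets stayed in; they were taken out before clustering, cell cycle and co-detection. Doublets were scored with a scrublet-type score against simulated pairs, and the highest scores, 0.8% per 1000 cells, were removed, which took 8.70% of LSK, 2.99% of CMP, 6.45% of GMP and 5.09% of MEP and left 9924, 3602, 7509 and 5964 cells.

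Counts of each gene were summed per library and divided by the library total (CPM). A sum has an exact Poisson interval, a ratio an exact conditional binomial interval and a share an exact Clopper-Pearson interval, all at 95% and covering counting error only. With 1 library per gate there is no test and no p-value. A gene counted as higher where the higher library had 50 CPM or more and the ratio was 2 or more, and a count under 3 was set to a floor of 3 counts in the ratio, also within list medians; the interval of such a ratio is that of the observed counts. Named genes were, per main contrast, the 10 with the largest log2 ratio in each direction by that rule, leaving out predicted genes, ribosomal protein genes and mitochondrial genes, all gate antigens, up to 4 members of each list with the highest CPM, the 7 co-detection pairs, the 5 with the largest ratio in each direction within a class and the 3 leading surface antigens per class; some of the genes this rule takes are not reported here. The rule, the lists, the markers and most of the alternatives were fixed before the data were examined. Gata1 in the contrast of GMP with MEP, Cdkn1b, Cdkn1c, Mki67, the genes given for barcodes outside the cells and the leading genes of clusters were named after their values had been seen. For the steps that give counts past the rule, data were simulated for the 4 main contrasts with 200 genes changed 3-fold among 27998. The changed genes were drawn from those with a mean of 50 CPM or more, and only counting noise was simulated. This gave 100% of the changed genes and 0 others, with interval coverage of 95.1, 95.5, 94.9 and 95.5%. Without variation between libraries, it checks the calculation and does not bear on false calls between single libraries.

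The lists fixed were gate antigens, lineage transcription factors, surface antigens, heme synthesis, iron uptake and storage, primary granule, MHC class II, interferon response, immediate early, ribosome biogenesis, glycolysis, cholesterol synthesis, cell cycle inhibitors, S phase and G2/M phase, and markers of HSC/multipotent, lymphoid-primed, granulocyte-monocyte progenitor, neutrophil, monocyte, dendritic, erythroid, megakaryocyte, basophil/mast, eosinophil, B, T/NK, macrophage, plasma and endothelial/stromal cells. A list's median log2 ratio was taken over members with a mean of 1 CPM or more in the 2 libraries, with 3 or more such members, and set against 10000 random lists matched on expression. Gene IDs were used as in the matrices; 27722 of 27998 are in GENCODE M21 (GRCm38), 26573 with the same symbol, and coordinates are from there. Reads of near-identical genes such as Hba-a1 and Hba-a2 can be split between them by the counting.

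Cells of the 4 libraries were clustered together without batch correction, since library and gate are the same thing. The steps were 2000 highly variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 with seed 0. A cluster could be named from a class where 3 or more of its markers had 10 CPM and a 2-fold excess over all other cells. The mean log2 ratio over all markers of the class with any count had to lead by 0.3. It was set against the next class with 3 or more such markers, or against 0 where there was none. More markers of the class than of any other also had to be among the 10 leading genes (or none of any class, with a mean of 1 or more). This naming rule was set after the clusters had been seen and tightened once. Classes with 100 or more cells in each of 2 libraries were compared by summed UMIs. Phases were called from S and G2/M gene scores, and co-detection was counted, after thinning each cell to 2000 UMIs.

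The alternatives were the Cell Ranger 2 rule for LSK cells (10873 barcodes), median-of-ratios and edgeR TMM factors, the mean over cells, minimums of 10 CPM or none, 1000 genes a cell or no filter, free RNA subtracted from LSK at 5%, no doublet removal, resolutions 0.5 and 2, 50 components, clustering without cell cycle genes, each library alone or cells thinned, and thinning to 1000 UMIs or none. Chosen after seeing the data were gene contrasts without doublets, naming by the highest marker mean alone and clustering without immediate early genes. The tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for the TMM factors.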

Results

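The data were droplet-based single-cell 3' RNA counts of haematopoietic stem and progenitor cells sorted from the bone marrow of wild-type C57BL/6 mice. The title of the series speaks of identifying and isolating such populations, and its design text names 4 sorted gates. LSK cells lacked lineage antigens and carried SCA1 and KIT, a compartment that holds the haematopoietic stem cells (HSC). The other gates were lineage-negative, KIT-positive and SCA1-negative, and were split by CD34 and the Fc gamma receptors CD16/32. Common myeloid progenitors (CMP) were CD34-positive and CD16/32-negative, granulocyte/monocyte progenitors (GMP) were positive for both, and megakaryocyte/erythroid progenitors (MEP) were negative for both. The labels list 5 samples, and the 2 CMP samples held identical matrices, so they were counted as 1 sample. Each gate was therefore 1 library, with no replicate check on any difference. Intervals given here are 95% intervals that cover counting error only, except where resampling is named.

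After filtering, 10870 LSK, 3713 CMP, 8027 GMP and 6284 MEP cells were kept. They held 75167959, 26919088, 73362645 and 80273121 molecules counted by unique molecular identifiers (UMIs). The median cell had 5991.5 UMIs in LSK, 6904 in CMP, 9100 in GMP and 12578 in MEP. The design text states 12185 CMP cells, while the CMP matrix used here held 3738 barcodes. The stated numbers of GMP and MEP cells, 8064 and 6370, equalled the barcodes of those matrices. Levels are given as counts-per-million (CPM) of the UMIs of the library, and 3 UMIs, the floor for genes with fewer, correspond to 0.0399, 0.111, 0.0409 and 0.0374 CPM in LSK, CMP, GMP and MEP.

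The transcripts of the sorting antigens followed the gates in the 4 libraries, except for that of CD32 in CMP. Ly6a, the gene of SCA1, had 78.2 CPM in LSK (76.2 to 80.2) against 1.49 in CMP (1.06 to 2.02), 1.10 in GMP (0.877 to 1.37) and 0.112 in MEP (0.0513 to 0.213). Cd34 had 399 CPM in LSK, 234 in CMP and 118 in GMP, but 0.498 in MEP (0.356 to 0.679). Fcgr3, the gene of CD16, had 208 CPM in GMP (204 to 211), 13.9 in CMP (12.5 to 15.3), 0.838 in LSK and 0.149 in MEP. Fcgr2b, the gene of CD32, had 61.5 CPM in GMP, 33.8 in CMP, 6.31 in LSK and 0.336 in MEP. It was seen in 41.1% of GMP cells and also in 20.1% of CMP cells, though that gate was CD16/32-negative. Kit, common to all gates, had 100.5 CPM in LSK, 46.8 in CMP, 34.9 in GMP and 46.8 in MEP. The median log2 ratio of the 7 antigens listed here was 0.77 in LSK over CMP. Ly6e, a relative of Ly6a that no gate used, had 380.3, 556, 559 and 213 CPM in LSK, CMP, GMP and MEP. Il7r, the receptor of early lymphoid progenitors, had 4.27 CPM in LSK (3.82 to 4.76) and 0.371 in CMP (0.178 to 0.683), while GMP held 1 UMI and MEP 0.212 CPM. On GRCm38 with the GENCODE M21 annotation, these protein-coding genes lie at chromosome 15, 74994877 to 74998031 (Ly6a), chromosome 1, 194938819 to 194961279 (Cd34), chromosome 1, 171051174 to 171064935 (Fcgr3), and chromosome 1, 170958617 to 170976547 (Fcgr2b). Kit lies at chromosome 5, 75574916 to 75656722, Ly6e at chromosome 15, 74955051 to 74959905, and Il7r at chromosome 15, 9505788 to 9530176.

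**Figure D1:**
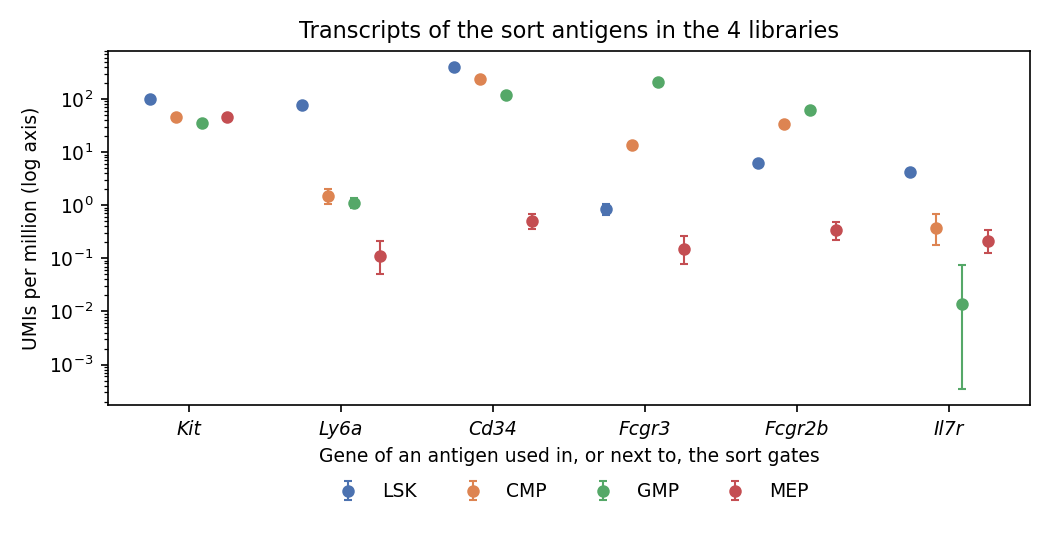
Counts-per-million (log axis) of Kit, Ly6a, Cd34, Fcgr3, Fcgr2b and Il7r in the LSK, CMP, GMP and MEP libraries; points are library totals and bars are 95% Poisson intervals (counting error only). Ly6a stood at 78.2 in LSK and at 1.49 or below in the other libraries, and Cd34 fell to 0.498 in MEP.

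Comparing LSK with CMP asks how the SCA1-positive compartment differed from the CD34-positive myeloid gate. Stem cell genes were far higher in LSK. Of 12 HSC/multipotent markers, 7 were at least 2-fold higher in LSK and none in CMP, with a median log2 ratio of 3.001. Mecom, a transcription factor needed by HSC, had 95.9 CPM in LSK and 2.27 in CMP, a log2 ratio of 5.40 (5.04 to 5.79). Hlf had 269 and 11.1 CPM (log2 4.59, 4.43 to 4.76), and Procr, which encodes the surface protein EPCR, had 56.7 and 1.78 CPM (log2 4.99, 4.58 to 5.43). Lymphoid-primed markers were also higher in LSK, 5 of 9 detected members by 2-fold, with a median of 1.72. Dntt, the terminal transferase of lymphoid precursors, had 272 CPM in LSK and 24.4 in CMP, and the cytokine receptor gene Flt3 had 131 and 39.9 CPM.

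Granulocyte and monocyte genes were higher in CMP. Of 10 granulocyte-monocyte progenitor markers, 7 were 2-fold higher in CMP, with a median log2 ratio of -2.66. The neutrophil elastase gene Elane had 5.32 CPM in LSK and 700.2 in CMP (log2 -7.04, -7.19 to -6.90), and the myeloperoxidase gene Mpo had 102.5 and 1761 CPM. Monocyte markers (median -3.55, 5 of 9 higher in CMP and 1 in LSK) included Irf8 at 57.4 and 624 CPM and Ly6c2 at 1.81 and 123 CPM. The member higher in LSK was Klf4, at 52.7 and 21.3 CPM, which was below 2-fold with either median-of-ratios or TMM factors. Medians were -4.25 for neutrophil markers (4 of 10 higher in CMP), -2.47 for basophil/mast markers (2 of 7) and -0.70 for primary granule genes (4 of 9). Erythroid and megakaryocyte markers went both ways around medians of -0.94 and -0.36. Car2 (1210 and 235 CPM) was higher in LSK, while Car1 (23.5 and 74.9 CPM) and Pf4 (88.5 and 339 CPM) were higher in CMP.

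Interferon response genes leaned towards LSK, with a median of 1.40 over 14 detected members, 4 of them 2-fold higher in LSK by CPM. Of these, Ifitm1 (log2 1.03), Ifitm3 (1.04) and Ifi203 (1.31) were below 2-fold with either median-of-ratios or TMM factors. Ifitm1 had 768 and 377 CPM and Ifitm3 720.2 and 350.5 CPM, whereas Ifitm2 had 703 and 880 CPM. Other genes with the largest ratios towards LSK were Myl10 (log2 5.50), Ltb (5.31), Stxbp4 (3.80), Shisa8 (3.48) and Tnip3 (3.39). Those with the largest ratios towards CMP were Hp (-6.36), F13a1 (-6.13), Ngp (-5.19), Slpi (-4.87), Ly86 (-4.64), Ms4a3 (-4.60), Camp (-4.52) and Ctsg (-4.21). The T/NK cell and endothelial/stromal marker lists had only 3 detected members each, with medians of 2.07 and 2.02, led by Lck (28.5 and 2.68 CPM) and Emcn (18.3 and 2.34 CPM). In all, 187 genes were higher in LSK and 83 in CMP by the fixed rule of 2-fold and 50 CPM, out of 3056 genes with 50 CPM in either library. That split depended on the scaling: median-of-ratios factors shifted all log2 ratios by -0.38 and TMM factors by -0.31, which left 20.4% and 25.3% of the genes past the rule higher in LSK, against 69.3% by CPM and 85.8% with a minimum of 10 CPM. With such factors the medians of the lineage transcription factors (0.28 by CPM), surface antigens (0.18), heme synthesis (0.16), glycolysis (0.18) and cell cycle inhibitors (0.16) turned negative, and with median-of-ratios factors so did MHC class II and dendritic markers (both 0.36) and immediate early genes (0.34), so no direction is drawn for these lists.

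Comparing CMP with GMP asks what changed with CD16/32 inside the CD34-positive SCA1-negative cells. Granule genes were higher in GMP, and immediate early genes, some MHC class II genes and a few megakaryocyte and erythroid genes were higher in CMP. Of 9 detected primary granule genes, 6 were 2-fold higher in GMP and none in CMP (median log2 -1.32). Elane had 700.2 CPM in CMP and 12374 in GMP (log2 -4.14, -4.16 to -4.12), Ctsg 1771 and 5613 CPM, Prtn3 1719 and 4994 CPM, and Mpo 1761 and 4405 CPM. Cebpe, a transcription factor of later granulocyte development, had 6.87 and 141 CPM (log2 -4.36). Medians were -1.42 for granulocyte-monocyte progenitor markers (7 of 10 higher in GMP), -1.67 for neutrophil markers (6 of 10) and -0.44 for monocyte markers (2 of 10). Ly6c2 was higher in GMP (123 and 1400 CPM), while Irf8 had 624 and 495 CPM. Eosinophil and basophil granule genes stood apart: the eosinophil granule gene Prg2 had 2 UMIs in CMP against 144 CPM in GMP (log2 -10.34, -13.97 to -9.07), and the basophil protease gene Prss34 had 0.186 and 65.8 CPM (log2 -8.47, -10.09 to -7.24). The eosinophil list (3 detected members) had a median of -4.65 and the basophil/mast list had a median of -0.75.

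On the CMP side, 11 of 14 immediate early genes, which respond quickly to stimulation, were 2-fold higher, with a median of 2.29. Egr1 had 225 and 9.12 CPM (log2 4.62, 4.51 to 4.74), Fos 798 and 204 CPM, and Jun 887 and 459.5 CPM. The chemokine genes Ccl3 (411 and 14.5 CPM), Ccl4 (344 and 7.97 CPM) and Cxcl2 (65.9 and 1.45 CPM) were among the 10 with the largest ratios. So was Id3 (54.9 and 0.109 CPM, log2 8.98, 7.99 to 10.19). Of 6 detected MHC class II genes, 3 were 2-fold higher in CMP (median 3.23), among them Cd74 at 214 and 9.23 CPM and H2-Aa at 108 and 5.22 CPM; these also lead the dendritic list (median 4.48). Megakaryocyte markers had a median of 5.73, though only 1 of 10 passed the rule, Pf4 at 339 and 4.36 CPM, and erythroid markers one of 3.38, with 2 of 11 past it, among them Car1 at 74.9 and 1.17 CPM. HSC/multipotent (1.49) and lymphoid-primed (2.35) medians were above 0, with Angpt1 at 74.5 and 8.78 CPM and Flt3 at 39.9 and 4.06 CPM. The interferon response and cell cycle inhibitor medians were 1.19 and 0.90, with 2 of 13 and 1 of 7 genes 2-fold higher in CMP, including Ifitm1 (377 and 71.7 CPM) and Cdkn1a (68.1 and 12.5 CPM). Glycolysis genes had a median of -0.48 and cholesterol synthesis genes one of 0.35. Macrophage (-2.61) and B cell (-0.20) lists rested on 3 low members each. By the fixed rule, 113 genes were higher in CMP and 82 in GMP, a split of 57.9% that fell to 43.5% with median-of-ratios factors (shift -0.16) and to 46.1% with TMM factors (shift -0.13), and rose to 77.2% with no minimum beyond 3 counts.

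Comparing CMP with MEP asks what separated the CD34-positive from the CD34-negative gate among cells low in CD16/32. Erythroid, heme and iron genes were higher in MEP. Of 13 detected erythroid markers, 12 were 2-fold higher in MEP and none in CMP, with a median of -4.82. Car1 had 74.9 CPM in CMP and 4513 in MEP (log2 -5.91, -5.98 to -5.85), and Klf1, a transcription factor of red cell development, had 12.3 and 422 CPM (log2 -5.10, -5.26 to -4.95). Of 8 detected heme synthesis genes, 5 were 2-fold higher in MEP and 1 in CMP (median -2.05), those in MEP including Alad (64.1 and 306 CPM) and Cpox (15.6 and 226 CPM). The iron list had 5 of 9 members higher in MEP (median -2.32), among them Tfrc, the transferrin receptor gene (13.8 and 90.03 CPM), and Glrx5 (227 and 818 CPM). The blood group gene Rhd (0.632 and 245 CPM), Ermap (0.706 and 261 CPM), Sphk1 (4 UMIs in CMP, 194 CPM in MEP) and Cldn13 (5 UMIs, 170.0 CPM) were among the 10 with the largest ratios towards MEP. Paqr9 had no UMI in CMP and 63.1 CPM in MEP, 566.5-fold higher against the floor of 3 counts (lower limit 460.5). Mt2, Slc25a21, Nxpe2, Slc38a5 and Add2 completed these, with log2 ratios between -8.70 and -7.57.

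Myeloid and immediate early genes were higher in CMP. All but 1 of the 9 detected primary granule genes were 2-fold higher in CMP (median 6.49), among them Mpo (1761 and 0.660 CPM, log2 11.38, 10.99 to 11.80) and Ctsg (1771 and 0.411 CPM). Medians were 7.52 for granulocyte-monocyte progenitor markers (9 of 10 past the rule), 8.48 for monocyte (5 of 9), 7.09 for neutrophil (4 of 10), 5.60 for basophil/mast (2 of 5) and 6.53 for lymphoid-primed markers (0 of 7). Mcpt8, a basophil protease gene, had 57.8 CPM in CMP and no UMI in MEP, 1547-fold higher against the floor of 3 counts (lower limit 1256). Of 14 immediate early genes, 12 were 2-fold higher in CMP (median 3.21), including Fos at 798 and 99.2 CPM. The chemokine genes Ccl3 (411 and 0.0872 CPM), Ccl4, Cxcl2 and Ccl9 were among the 10 with the largest ratios, with F13a1 (1 UMI in MEP; log2 11.39, 10.50 to 18.28), Emb (10.03) and Ly6c2 (9.95). Cell cycle inhibitor genes (median 1.91, 3 of 7 higher in CMP) included Cdkn1a at 68.1 and 3.61 CPM. MHC class II genes had a median of 3.34, dendritic markers one of 3.50 and the megakaryocyte list one of 1.75, with Pf4 at 339 and 75.9 CPM but Gp5 at 13.9 and 37.1 CPM. As above, Cd74 and Pf4 in CMP lay in few of its cells. Ribosome biogenesis genes had a median of -0.82, with Npm1 at 2017 and 4313 CPM. The plasma cell list (3 members) had a median of 0.33. The rule took 351 genes higher in CMP and 327 in MEP, 51.8% against 40.5% with median-of-ratios factors (shift -0.14) and 71.9% with no minimum beyond 3 counts.

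GMP and MEP differed most among the 4 main contrasts, with 375 genes higher in GMP and 370 in MEP. Granule genes were higher in GMP: all 9 detected primary granule genes were 2-fold higher in GMP (median 7.35), with Elane at 12374 and 1.87 CPM (log2 12.69, 12.46 to 12.93), Ctsg at 5613 and 0.411 CPM (log2 13.74) and Mpo at 4405 and 0.660 CPM. Ly6c2 (log2 13.46), Hp (12.14), Trem3 (11.54), Prg2 (11.50) and Cebpe (11.47) were next to them, and F13a1 had 1 UMI in MEP (log2 12.44, 11.54 to 19.33). Mcpt8 had 140 CPM in GMP and no UMI in MEP, 3742-fold higher against the floor of 3 counts (lower limit 3043). On the MEP side, 12 of 13 erythroid markers were 2-fold higher (median -8.56), with Car1 at 1.17 and 4513 CPM (log2 -11.91, -12.23 to -11.61) and Klf1 at 1.12 and 422 CPM. Sphk1, Slc25a21 and Add2 had no UMI in GMP and were 4737-, 2049- and 1904-fold higher in MEP against that floor (lower limits 3852, 1666 and 1548). Slc38a5 and Paqr9 had 3 UMIs each in GMP, with log2 ratios of -11.51 (-13.79 to -9.96) and -10.59 (-12.87 to -9.04), and those of Rhd, Ermap, Tspo2 and Cldn13 lay between -11.13 and -10.80.

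Of the metabolic lists, heme synthesis had a median of -1.94, yet Alas1, the housekeeping form of the first enzyme of the pathway, had 354 CPM in GMP and 12.3 in MEP (log2 4.84, 4.75 to 4.93). Iron genes had a median of -2.36, with Fth1 at 1595 and 3565 CPM. Glycolysis genes had a median of 1.12, 5 of 13 being 2-fold higher in GMP and 1 in MEP, with Pkm at 775 and 9.56 CPM and Pgam1 at 621 and 51.4 CPM, while Ldha had 789 and 1031 CPM. Cholesterol synthesis genes had a median of -0.23 (percentile 29.1 among random lists matched on expression), with 1 of 14 higher in GMP and none in MEP. Ribosome biogenesis genes had a median of -0.84, 6 of 18 being 2-fold higher in MEP, among them Ncl at 855 and 1808 CPM. Lineage transcription factors split evenly, 5 of 18 on each side: Spi1 had 251 and 6.03 CPM, Irf8 495 and 3.10, Gata1 1.55 and 125, and Klf1 1.12 and 422. The contrasts of LSK with GMP and with MEP gave 656 and 1000 genes. By CPM 64.0% and 54.8% of these were higher in LSK, against 17.9% and 20.2% with median-of-ratios factors (shifts -0.54 and -0.52) and 24.1% and 23.9% with TMM factors (shifts -0.45 and -0.44). With a minimum of 10 CPM the shares were 80.4% and 73.1%, and with none beyond 3 counts 84.5% and 83.7%.

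**Figure D2:**
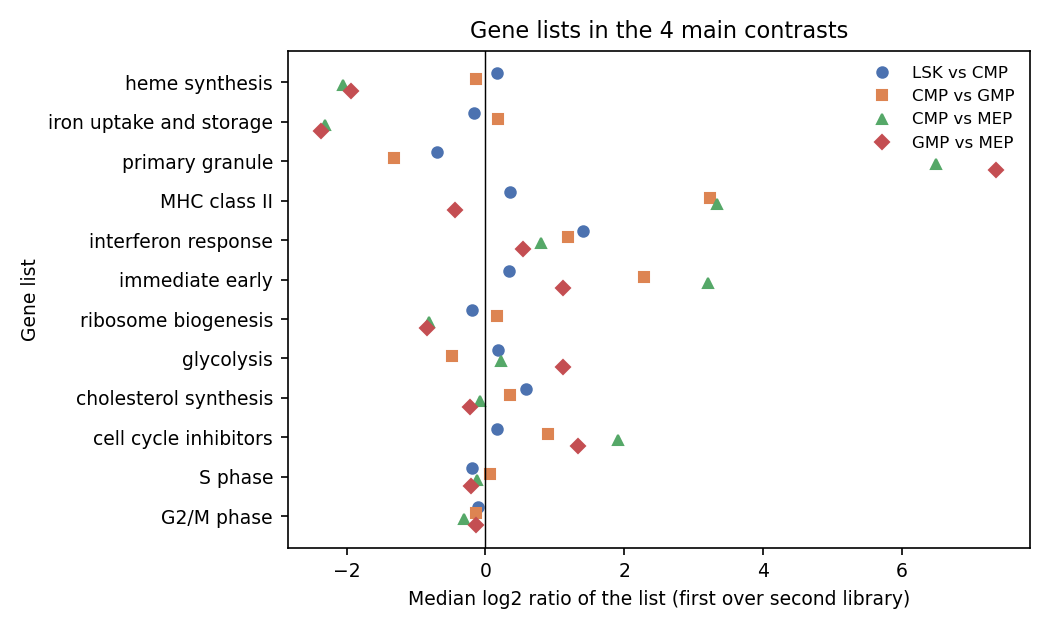
Median log2 ratio of 12 gene lists (first over second library) in the contrasts LSK vs CMP, CMP vs GMP, CMP vs MEP and GMP vs MEP; each point is the median over the detected members, by CPM. Primary granule genes reached 7.35 in GMP over MEP and heme synthesis -2.05 in CMP over MEP; the LSK vs CMP points shift by -0.38 with median-of-ratios factors, which turns heme synthesis, MHC class II, immediate early, glycolysis and cell cycle inhibitors below 0, as it does S phase in CMP vs GMP.

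Clustering the 4 libraries together gave 22 clusters, most of them made up of cells of 1 library, so that a cluster and a library often cannot be separated. MEP was the most uniform: 95.9% of its cells (95.4 to 96.4) were erythroid-like, in clusters 5, 8, 9, 15 and 20, a share that stayed between 95.4 and 95.9% under 10 alternatives. A megakaryocyte-like cluster, number 13, held 3.35% of MEP (2.91 to 3.84), 3.86% of CMP (3.25 to 4.54) and 5.90% of LSK (5.45 to 6.39), and 8 GMP cells. Basophil/mast-like cells made up 16.5% of CMP (15.3 to 17.8), nearly all in cluster 16, and 3.72% of GMP (3.30 to 4.17), nearly all in cluster 17, whose leading genes include the eosinophil genes Prg2, Prg3 and Epx. Cluster 16 met the naming rule with 4 markers and a mean log2 ratio of 1.09, ahead of 0.55 for megakaryocyte markers. In CMP the basophil/mast-like cells had 91.5 CPM of Fcer1a, but 38.0 of Mcpt8, below the 57.8 of the whole library. They also had 805 CPM of the erythroid marker Car2, so the name is a weak one there. Monocyte-like clusters 3 and 4 held 56.5% of GMP (55.3 to 57.6). In LSK, 29.5% were HSC/multipotent-like (28.6 to 30.4) and 31.0% lymphoid-primed-like (30.1 to 31.9). Of the latter, 1631 of 3076 cells lay in cluster 7, whose leading genes include the histone genes Hist1h2ap and Hist1h2ae beside Dntt, and 81.8% of these 1631 were called G2/M at 2000 UMIs (79.8 to 83.6; 80.7% unthinned). Dendritic-like cells made up 2.58% of CMP (2.09 to 3.15), neutrophil-like cells 0.466% of GMP and T/NK cell-like cells 0.171% of LSK. The gates set these shares, and the naming rule, fixed after the clusters had been seen, left 32.8% of LSK, 73.3% of CMP, 39.0% of GMP and 0.134% of MEP unnamed.

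Most class shares other than that of the erythroid-like cells moved with the clustering. The monocyte-like share of CMP, 1.78% in the main clustering, was between 18.5 and 73.4% under all 10 alternatives. Clusters 6 and 14, with 47.6 and 24.01% of CMP, had the monocyte list as their best match without meeting the naming rule, and named by the highest marker mean alone they brought the share to 73.4%. The HSC/multipotent-like share of LSK ranged from 0 to 59.3% and the lymphoid-primed-like share from 23.99 to 81.4%. The megakaryocyte-like share of LSK, 5.90% in the main clustering, ranged from 0.292 to 7.03% and was 2.34% or less under most alternatives. That of CMP ranged from 3.44 to 13.2%. The basophil/mast-like share of CMP ranged from 1.82 to 26.5%, that of GMP from 3.12 to 3.90%, the monocyte-like share of GMP from 25.2 to 57.7% and the megakaryocyte-like share of MEP from 2.35 to 3.57%.

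**Figure D3:**
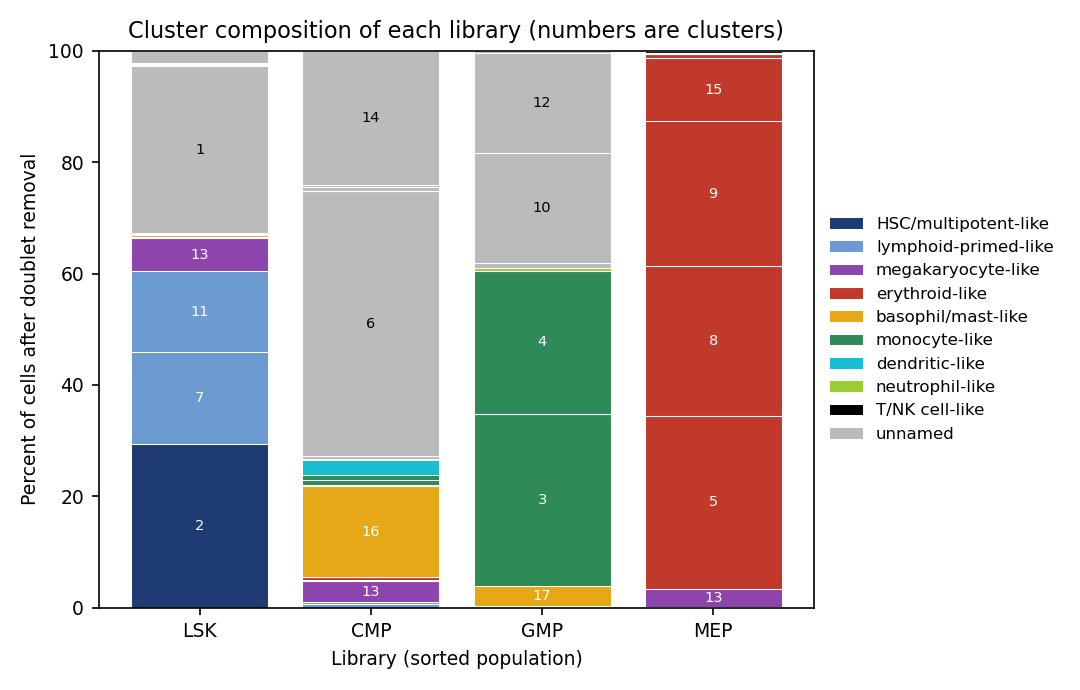
Percent of the cells of each library (LSK, CMP, GMP, MEP; after doublet removal) in each cluster, stacked and coloured by the class name; numbers are clusters, shown where a segment holds 3% or more. Erythroid-like clusters filled 95.9% of MEP, and 73.3% of CMP stayed unnamed.

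**Figure D4:**
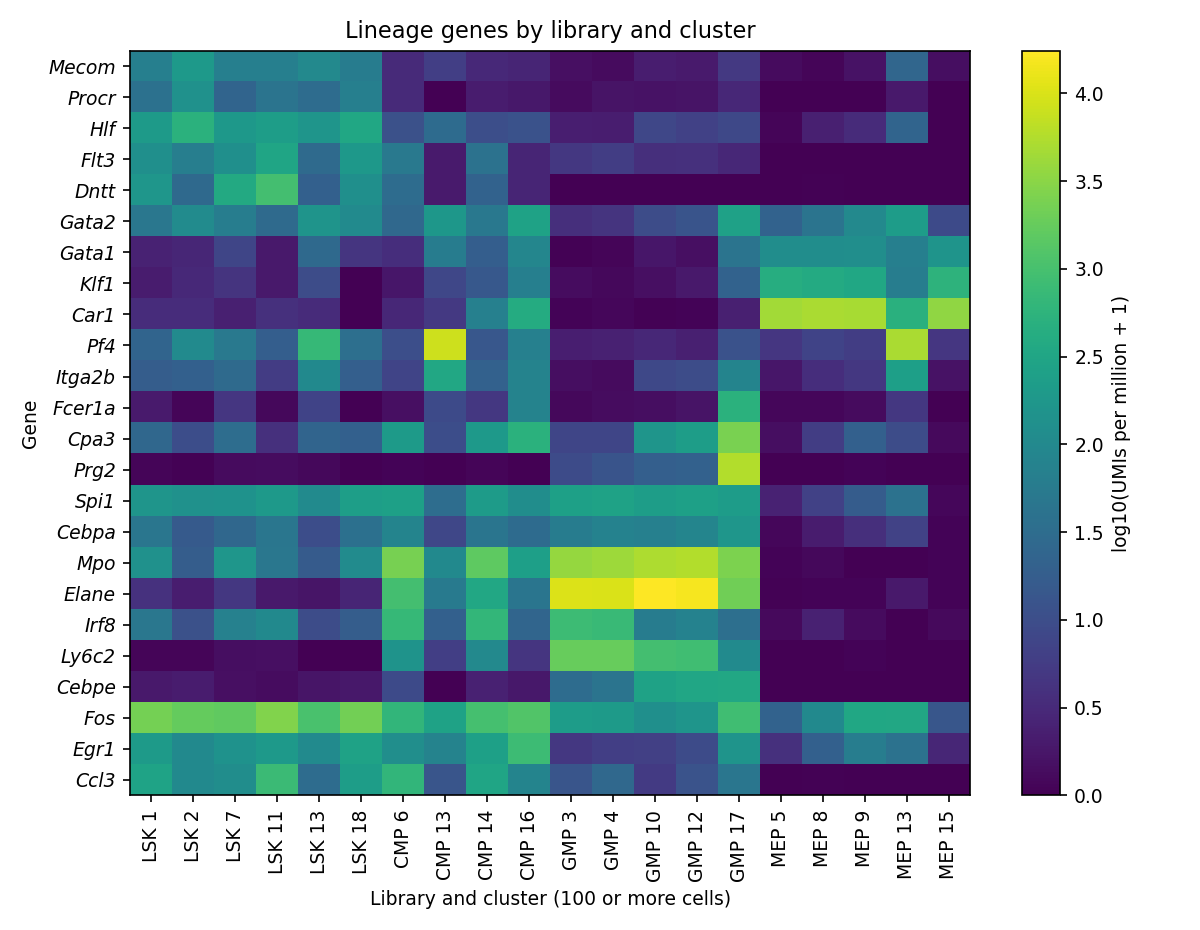
Levels of 24 lineage and immediate early genes, as log10 of counts-per-million (CPM) plus 1 (colour), in each library and cluster with 100 or more cells; many of these genes took part in the clustering. Car1 was high in the MEP clusters, Pf4 in cluster 13 of each library, and Prg2 in GMP cluster 17.

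Cells of the same class could be compared between gates where each library held 100 or more of them. Between the megakaryocyte-like cells of CMP and MEP, Car1 had 4.04 CPM in 139 CMP cells and 492 CPM in 200 MEP cells (log2 -6.93, -8.81 to -5.56), and Klf1 had 7.07 and 60.7 CPM (log2 -3.10, -4.47 to -1.97). The 29 T/NK cell-like and dendritic-like MEP cells had 819 CPM of Car1 and 73.8 of Klf1, so neither gene was above background in the megakaryocyte-like MEP cells. In those of CMP, Mpo had 102 CPM against no UMI in MEP and Ctsg 80.8 CPM against 1 UMI (log2 4.81, 3.87 to 11.71). Mpo was seen in 16.1% of these CMP cells at 2000 UMIs and in 15.4% of the dendritic-like CMP cells (median depths 6885 and 4706 UMIs), a similar share. Free RNA of CMP was not measured, since every barcode of its matrix was taken as a cell. These values therefore cannot tell free Mpo or Ctsg RNA from transcripts of the cells. The fixed rule took 63 genes higher in CMP and 38 in MEP, 101 in all, against 161 at resolution 0.5 and 345 with thinned cells. Pf4 itself differed in the 586 LSK cells of the cluster, with 693 CPM against 8459 in CMP, and H2-Aa had 105 and 3.03 CPM. These LSK cells were 5.90% of their library, but the class held 2.34% or less of LSK under most alternatives. Which LSK cells belong to it is thus unsettled, and the values do not show 1 class differing with its gate. LSK against CMP gave 317 genes and LSK against MEP 191, which fell to as few as 176 and 58 under other clusterings. Between the basophil/mast-like cells of CMP (cluster 16) and GMP (cluster 17), Car1 had 396 and 3.93 CPM and Aqp1 78.2 and 2.62 CPM, while Prss34 had 2.16 and 2916 CPM, Mcpt8 38.0 and 3068 CPM, and Prg2 no UMI and 5664 CPM. Few of the cells carried the last: 17.5% of cluster 17 in GMP had a UMI of Prg2 or Epx at 2000 UMIs and 24.9% unthinned, against 2.22 and 8.66% of the monocyte-like GMP cells (median depths 5290 UMIs for the class and 9262). That contrast took 181 genes higher in CMP and 152 in GMP, and 216 in all with each library clustered alone. It sets 583 CMP cells of cluster 16 mainly against 269 GMP cells of cluster 17. The clustering had already split these cells by their genes, so the counts do not show 1 class differing with its gate.

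Transcripts of surface antigens usable for sorting, from a list of 43, were compared where they reached 20 CPM in a class, between that class and the other cells of its library. In MEP, megakaryocyte-like cells had Esam at 57.8 CPM against 0.164 in the other cells. Itgb3 had 23.1 CPM against no UMI, 565-fold higher against the floor of 3 counts (log2 9.14, lower limit 8.73). Erythroid-like MEP cells had Tfrc at 90.9 against 28.2 CPM, Epor at 94.8 against 31.4 and Cd24a at 396 against 158. In CMP, Esam (41.4 and 1.18 CPM) and Itga2b (348 and 17.9) set the megakaryocyte-like cells apart, and Fcer1a (91.5 and 2.02) and Cd63 (740.1 and 181) the basophil/mast-like cells. In GMP, Fcer1a (508 and 0.401 CPM) and Il1rl1 (22.9 and 0.123) were highest in basophil/mast-like cells, and Csf1r (29.5 and 5.05), Cd52 (394 and 160) and Ly6c2 (1804 and 849) in monocyte-like cells. In LSK, HSC/multipotent-like cells had Procr at 141 against 32.8 CPM and Esam at 66.9 against 19.7, lymphoid-primed-like cells had Flt3 at 187 against 95.5, and megakaryocyte-like cells had Itga2b at 100.5 against 18.8. Several of these genes took part in the clustering, so the values describe the clusters and are no separate check of them.

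Cell cycle genes took a larger share of UMIs in the SCA1-negative gates. The G2/M list had 0.544% of UMIs in LSK (0.542 to 0.546), 0.690% in CMP, 0.752% in GMP and 0.899% in MEP (0.897 to 0.901), and the S phase list 0.333, 0.396, 0.376 and 0.418%. Mki67, a gene of cycling cells, had 99.8, 104, 115 and 204 CPM, and Cdkn1c, an inhibitor of the cycle linked to quiescent HSC, 25.04, 1.09, 0.513 and 0.821 CPM. The inhibitors Cdkn1a, at 29.6, 67.8, 12.3 and 3.67 CPM, and Cdkn1b, at 28.6, 29.95, 8.98 and 10.2 CPM, did not follow that order. With each cell thinned to 2000 UMIs, which left out 36 CMP cells and none elsewhere, 39.6% of LSK (38.6 to 40.6), 68.3% of CMP (66.7 to 69.8), 86.2% of GMP (85.4 to 87.0) and 89.2% of MEP (88.4 to 90.01) were called S or G2/M. Unthinned, the shares were 39.9, 73.9, 91.6 and 92.8%. Free RNA can add to such calls and was not separated from them. Between the SCA1-negative gates, S phase medians were 0.07 in CMP over GMP (below 0 with either other scaling), -0.12 in CMP over MEP and -0.20 in GMP over MEP, and the G2/M medians -0.14, -0.32 and -0.14. Among random lists matched on expression these lay at percentiles 76.7, 65.8 and 59.15 for S phase and 0.13, 3.22 and 63.4 for G2/M, and genes with 50 CPM had medians of -0.18 in CMP over MEP and -0.21 in GMP over MEP. Neither list thus stood apart from other genes in GMP over MEP, nor did S phase in CMP over GMP or over MEP. In LSK over CMP the S phase median was -0.20 by CPM, -0.57 with median-of-ratios and -0.51 with TMM factors, and the G2/M median -0.11, -0.48 and -0.42; the percentiles by CPM were 0.13 and 0.52.

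Co-detection of lineage genes in single cells was counted after thinning to 2000 UMIs. In CMP, erythroid or megakaryocyte genes met Mpo less often than the product of their shares. Gata1 and Mpo were seen together in 39 of 3566 cells (1.09%, 0.779 to 1.49) where 100.4 were expected, 0.389 times, and Klf1 with Mpo in 34 where 98.97 were expected, 0.344 times. Pf4 met Mpo in 75 cells where 160.0 were expected, 0.469 times, and Gata1 met Spi1 in 29 where 47.6 were expected, 0.609 times. Unthinned ratios were higher, 0.602, 0.551 and 0.764 for the pairs with Mpo, with 4.72, 2.89 and 7.08% of cells holding both. Free RNA bears on these counts: Mpo had a UMI in 27.3% of the Gata1-positive CMP cells (20.2 to 35.3; median depth 4639 UMIs) and 24.1% of the Klf1-positive ones (17.3 to 32.0; 4328 UMIs), beside 16.1% of the megakaryocyte-like (10.3 to 23.3; 6885 UMIs), 15.4% of the dendritic-like (8.67 to 24.5; 4706 UMIs) and 25.04% of the basophil/mast-like CMP cells (21.6 to 28.8; 3540 UMIs), with overlapping intervals. In Pf4-positive CMP cells the share was 32.9% (26.8 to 39.4; 6043.5 UMIs), an interval above those of the megakaryocyte-like and dendritic-like cells that overlapped that of the basophil/mast-like cells. Gata1 had a UMI in 0 of 91 dendritic-like CMP cells, for which 3 counts allow a share of cells with a UMI of up to 3.30%. Gata2 with Cebpa was at 0.934 times the expected number in CMP but at 2.23 times in GMP, in 66 cells where 29.7 were expected, and at 0.648 in LSK; the unthinned shares were 5.94, 4.08 and 4.48%. Pf4 with Klf1 was at 0.441 times the expected number in MEP (48 cells), 0.998 in CMP (9 cells) and 1.65 in LSK (8 cells), with 4.91, 0.833 and 0.524% of cells unthinned. Flt3 with Gata1 in LSK was at 0.351 (7 cells), with 0.373% unthinned.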

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

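Chosen only after the result was seen were the tests of immediate early genes between CMP and MEP and in the basophil/mast-like cells of CMP and GMP, of free RNA and of doublet droplets, and the criteria for free RNA and for the basophil and eosinophil doublets were reworded with their values in view; the tests of immediate early genes in the monocyte-like cells of CMP and GMP and of separate basophil and eosinophil progenitors were set before.

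The LSK matrix holds barcodes beyond the cells, 508788 of them with 1 or more UMIs, and these carry 22.7% of its UMIs. In the 1100 barcodes with at least 650 UMIs that were not taken as cells, Hbb-bs, a globin gene, had 336 CPM (304 to 370.2) against 4.11 in the cells. S100a8, a neutrophil gene, had 495 CPM (456 to 536) in the same barcodes against 23.0 in the cells. Both genes were picked after their values had been seen, and Cd34 there (382 CPM) was close to its level in the cells (399 CPM).

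The immediate early genes stood higher in CMP than in MEP and GMP. A cause that acts on the whole library alike, such as handling or free RNA, would raise them in every class. The intervals of the medians below come from resampling the genes of the list and do not cover counting error. Clustered without these genes, megakaryocyte-like cells gave a median log2 ratio of CMP over MEP of 0.11 (-0.06 to 0.87; 136 and 199 cells) against 3.13 in the whole libraries, which argues against such a cause as the whole of that difference; dendritic-like cells gave 1.33 (0.90 to 2.20; 93 and 18 cells). Monocyte-like cells (755 and 4153) gave 2.14 for CMP over GMP (1.47 to 3.31) against 2.27 in the whole libraries. Basophil/mast-like cells (599 and 283) gave 1.36 (0.54 to 2.01), below it. In the main clustering that class set cluster 16 of CMP mainly against cluster 17 of GMP, so it is a weak comparison of like cells. For CMP over GMP a library-wide cause thus stays open. A difference of cell state between the gates stays open as well, untested, since each gate was 1 library.

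Megakaryocyte-like cells of MEP held UMIs of erythroid genes. Their excess over the CMP cells of the class, as a percent of the erythroid level and without Car2, was 11.6 (10.8 to 12.5), below the 17.3 (14.7 to 20.1) of 29 T/NK cell-like and dendritic-like MEP cells, so free RNA may account for it. For Car2 the excess was 30.5 (28.5 to 32.5) against 14.5 (11.4 to 18.1), above the free RNA level with CMP cells as the baseline. LSK cells of the class had 1720 CPM of Car2 against 1831 in MEP and 543.5 in CMP, so a level near that of MEP was also seen in LSK. Car2 was higher in the whole LSK library than in CMP as well. The excess of Car2 in MEP thus rests on CMP as the baseline, and these values cannot tell whether free RNA reaches it. The 20 cells with the most Car1 held 30.9% of the Car1 UMIs of the class, which argues against droplets with an erythroid cell as the source of most of them. A shared progenitor state stays open, as a hypothesis.

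Cluster 17 of GMP held basophil and eosinophil transcripts. Cells with a UMI of both kinds (Prss34 or Mcpt8, and Prg2 or Epx) numbered 35 against 28.5 expected, 1.23 times (0.872 to 1.67). Separate progenitors joined in 1 cluster would give fewer. Mcpt8 was not confined to these cells, however. The basophil/mast-like GMP cells held 4686 of its UMIs, and the GMP library, doublets included, held 10260. An eosinophil progenitor with Mcpt8 would count as both kinds, so the count does not decide on separate progenitors. A basophil gene was seen in 60.6% and an eosinophil gene in 17.5% of these 269 cells, against 5.28 and 2.22% of the monocyte-like GMP cells, whose depth was higher (median 9262 UMIs); unthinned, these were 75.5 and 24.9% against 19.2 and 8.66%, and the ratio was 1.19. Cells with both had 1.17 times the median UMIs of cells with 1 kind (0.944 to 1.40, from resampling the cells), which argues against doublets. A common basophil and eosinophil progenitor is a hypothesis only, found and tested on the same cells, and separate progenitors stay open as well.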

How the results depend on the processing

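Chosen only after the results were seen were naming by the highest marker mean, clustering without immediate early genes and gene contrasts without doublets. With 1 library per gate no difference between gates was tested against replicates, and no replicate could be left out. No paired analysis was possible because each gate was 1 library and no value comes from a test. Of the results that answer a comparison, 177 values under alternatives stayed within 1.5 times the main count or within the main interval and 91 did not. Of single named genes 719 stayed and 81 moved, of list medians 799 and 231, and of the co-detection ratios checked outside CMP 19 and 5. The 28 gate antigen levels stayed under the 1 alternative run for them, no filter on cells. No named gene or list with a drawn direction reversed. Depth limits genes under the floor of 3 counts. Except for the minimums, where more genes entered by construction, the cause was not tested.

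Genes past the rule, in the order LSK vs CMP, CMP vs GMP, CMP vs MEP, GMP vs MEP, LSK vs GMP and LSK vs MEP, numbered 270, 195, 678, 745, 656 and 1000 in the main contrasts. They numbered 1123, 578, 1851, 1909, 2073 and 2738 with a minimum of 10 CPM, and 4464, 2918, 5365, 5383, 6537 and 7597 with none beyond 3 counts. Median-of-ratios factors gave 991 for LSK vs GMP and 1536 for LSK vs MEP.

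Class shares are percent of the library. Without doublet removal, LSK was 34.3 HSC/multipotent-like, 23.99 lymphoid-primed-like and 1.06 megakaryocyte-like, CMP was 21.01 monocyte-like, and megakaryocyte-like cells differed by 184 genes in LSK vs CMP and 93 in LSK vs MEP. At resolution 0.5, LSK was 16.2 HSC/multipotent-like, 81.4 lymphoid-primed-like and 1.16 megakaryocyte-like, CMP 8.72 megakaryocyte-like and 69.2 monocyte-like and GMP 57.7 monocyte-like, with 179 (LSK vs CMP), 161 (CMP vs MEP) and 58 (LSK vs MEP) megakaryocyte-like genes. At resolution 2, LSK was 54.4 HSC/multipotent-like, 35.6 lymphoid-primed-like and 0.292 megakaryocyte-like, CMP 26.5 basophil/mast-like and 38.3 monocyte-like, GMP 30.7 monocyte-like and MEP 2.38 megakaryocyte-like, with 220 basophil/mast-like genes in CMP vs GMP. With 50 components, LSK was 0 HSC/multipotent-like and 0.302 megakaryocyte-like, CMP 19.5 and GMP 53.2 monocyte-like, and MEP 2.35 megakaryocyte-like. Without cell cycle genes, LSK was 9.80 HSC/multipotent-like and 1.19 megakaryocyte-like, CMP 22.9 basophil/mast-like and 18.5 monocyte-like and GMP 38.8 monocyte-like, with 176 (LSK vs CMP) and 58 (LSK vs MEP) megakaryocyte-like genes. With each library alone, LSK was 33.4 HSC/multipotent-like, 26.7 lymphoid-primed-like and 7.03 megakaryocyte-like, CMP 5.89 and GMP 3.12 basophil/mast-like, and CMP 42.2 and GMP 25.2 monocyte-like, with 216 basophil/mast-like genes.

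With cells thinned to 2000 UMIs, LSK was 35.8 lymphoid-primed-like and 2.17 megakaryocyte-like, CMP 1.82 basophil/mast-like, 13.2 megakaryocyte-like and 46.9 monocyte-like, and GMP 3.25 basophil/mast-like and 53.2 monocyte-like, with 345 megakaryocyte-like genes in CMP vs MEP. With the Cell Ranger 2 rule, LSK was 37.2 lymphoid-primed-like and 2.17 megakaryocyte-like, CMP 19.5 and GMP 53.4 monocyte-like, with 106 megakaryocyte-like genes in LSK vs MEP. Named by the highest marker mean, LSK was 31.7 HSC/multipotent-like and 61.04 lymphoid-primed-like, and CMP 73.4 and GMP 57.7 monocyte-like. Without immediate early genes, LSK was 59.3 HSC/multipotent-like, 36.97 lymphoid-primed-like and 2.34 megakaryocyte-like, and CMP 20.96 and GMP 55.3 monocyte-like, with 116 megakaryocyte-like genes in LSK vs MEP. Fewer than 100 cells left no value for the LSK megakaryocyte-like contrasts at resolution 2 and with 50 components, and for the basophil/mast-like contrast with thinned cells.

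Cells called S or G2/M were 37.6% of LSK, 62.7% of CMP, 77.9% of GMP and 85.7% of MEP at 1000 UMIs a cell, and 73.9% of CMP, 91.6% of GMP and 92.8% of MEP without thinning. Pf4 with Mpo in CMP was at 0.280 times the expected number at 1000 UMIs, and without thinning Gata1, Klf1 and Pf4 with Mpo were at 0.602, 0.551 and 0.764.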

Other observations

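No test was run on these values, which were chosen only after they were seen.

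Genes per cell at equal depth did not follow the unthinned order. Thinned to 2000 UMIs, the median cell showed 1007 genes in LSK (quartiles 978 and 1036), 974 in CMP, 966 in GMP and 997 in MEP, while unthinned medians were 2124, 2206, 2513 and 3090. Cluster 13, the megakaryocyte-like cells, had 1025 genes in LSK, 1012 in CMP and 1023 in MEP, above the median of each library. GMP cluster 12, led by Cebpe, had 952, the lowest of the clusters with 100 or more cells. LSK also had the most genes with a UMI in the library, 17475 against 15378 in CMP, 15766 in GMP and 15542 in MEP.

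Some small clusters are given as values. Cluster 22 held 17 LSK, 13 MEP and 1 CMP cells led by Tcf7, Ccl5, Ncr1 and Xcl1, genes of natural killer and T cells, and its share was 0.171% of LSK (0.0998 to 0.274) and 0.218% of MEP (0.116 to 0.372). Cluster 19, led by Batf3, Cd74 and H2-Aa, held 93 CMP, 19 LSK, 16 MEP and 8 GMP cells. Cluster 18 held 226 LSK cells (2.28%) led by the histone genes Hist1h2bc and Hist1h1c and by Ifi27l2a. No explanation of these groups was tested.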
